A study of Mus musculus with 12 samples.

How the data were processed

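Gene expression was measured on 12 Affymetrix mouse arrays of cultured bone marrow progenitor cells that carried retroviral Hoxa9. Per the labels, total RNA was extracted with an RNeasy Plus kit, fragmented and labelled with biotin. The donor mice were labelled female, 12 weeks old and treated with fluorouracil before marrow was taken. The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, these values were made with RMA in the Affymetrix Expression Console, whose versions are not given in the sources used here. RMA corrects background, quantile-normalizes the arrays at the level of single probes and summarises each probe set. No value was missing among the 23332 probe sets, and none of the 66 pairs of arrays held identical values. For arrays, their number limits the precision, and the groups here hold 1 to 3 of them.

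Probe sets were named from the platform annotation. It gave 1 gene symbol to 14996 probe sets, several to 1019 and none to 7317. The 16015 probe sets with at least 1 symbol were tested, and genes are named only from probe sets with 1 symbol, of which 14941 were found in the mouse gene table by gene identifier. No probe set is named for the miR-155 precursor or its host gene, so the level of miR-155 itself was not measured here. Where several probe sets share a symbol, the one of highest mean level stands for the gene.

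The labels give 5 groups. Hoxa9 with the empty vector MIG in wild-type cells has 3 arrays, Hoxa9 with miR-155 in wild-type cells 3, and Hoxa9 with MIG in miR-155 knockout cells 3. Hoxa9 with Meis1 has 1 array and Hoxa9 with the empty vector MIY has 2. The 6 comparisons were fitted with limma 3.58.1 in R 4.3.3. A mean was fitted for each group over all 12 arrays, so the groups share 1 estimate of the spread with 7 residual degrees of freedom and 3.06 more from the prior. P-values were adjusted by the Benjamini-Hochberg method over the 16015 probe sets, and a gene was called changed at an adjusted p under 0.05. Errors of log2 changes are limma's standard errors. Errors of levels are standard deviations between arrays. The single Meis1 array was set against the equally weighted mean of both empty-vector groups, because the labels do not say which belongs to it, and this array is assumed to vary like the other groups.

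A set of 19 gene lists was fixed before the data were examined, as were the design, the rule for named genes and most other settings. The lists were published direct targets of miR-155, stem and progenitor genes, genes tied to Hoxa9 and Meis1 leukaemia, primary granule genes, late granulocyte genes, monocyte and macrophage genes, MHC class II and dendritic cell genes, mast cell and basophil genes, eosinophil genes, red cell and megakaryocyte genes, lymphoid genes, stromal genes, interferon-stimulated genes, inflammatory genes, cell cycle genes, p53 targets, hypoxia and glycolysis genes, cholesterol synthesis genes, and immediate early and heat shock genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 19 lists. Camera asks whether a list moved more than the other genes did. Camera with an estimated correlation and fry were run beside it. Members were counted as changed both in the test over all genes and adjusted over the list alone.

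The rule for named genes took, for each comparison, the 10 highest and 10 lowest log2 changes among called genes whose arrays did not overlap between the groups, without predicted genes. It also took up to 4 members with the smallest p in each list past the list test, the perturbed genes and 6 known miR-155 targets or myeloid regulators in every comparison, and genes called in opposite directions with gain and loss of miR-155. Where fewer than 5 genes passed, the 10 smallest p-values were to be named as not passing, which did not arise. Other names belong to counts or groups of 5 or fewer members, or were chosen after their values were seen. For 3 comparisons the median change of all genes lay more than 0.1 from 0 on the log2 scale. There, each array was shifted so that its median difference to the mean array was 0, a setting chosen after the data were seen, and the changes of genes and lists are given relative to that shift.

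The fit and the list test were tested on simulated data, with 200 of 16015 genes changed. At a log2 change of 1, the comparison of miR-155 with MIG recovered 94% of the changed genes, that of the knockout with MIG 92%, that of miR-155 with the knockout 90%, that of Meis1 with the controls 84%, that of miR-155 with MIY 92%, and that of MIY with MIG 96%. At a log2 change of 0.5 the shares were 52%, 48%, 47%, 7%, 36% and 37% in the same order. False calls made up 2.67%, 5.41%, 4.20%, 2.15%, 3.76% and 10.1% of the calls. The simulated list shifted by -0.5 was called, and no other list was. The simulated genes were drawn independently, whereas in the data the estimated correlation within a list reached 0.72. The simulation therefore does not test how often camera calls unshifted lists of correlated genes.

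The alternatives tried were all probe sets, a filter on low levels, 3 other scalings of the arrays, another estimate of the spread, weights per array, a fold minimum, another threshold, fits on fewer arrays, a block for the replicate number, other controls for Meis1, and leaving out each array in turn. A search for seed matches of miR-155 in 3' untranslated regions had been planned and was not run, because no genome or transcript sequence was used here. Figures were drawn with matplotlib 3.10.9.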

Results

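Expression of 16015 probe sets with a gene symbol was compared between 5 groups of mouse bone marrow progenitor cultures that all carried Hoxa9, a homeobox gene that drives growth of myeloid progenitors. There were 3 arrays of Hoxa9 with the empty vector MIG, 3 of Hoxa9 with miR-155, 3 of Hoxa9 with MIG in miR-155 knockout cells, 1 of Hoxa9 with the cofactor Meis1, and 2 of Hoxa9 with the empty vector MIY. The small number of arrays limits the precision, most of all for the single Meis1 array.

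Hoxa9 read 13.25 ± 0.03 (log2, SD, n = 3) in MIG, 13.22 ± 0.02 (n = 3) with miR-155, 13.21 ± 0.02 (n = 3) in the knockout, 13.34 ± 0.10 (n = 2) in MIY and 13.07 on the Meis1 array, near the highest values of the arrays (13.6 to 13.8), where a probe set can saturate. Meis1 read 12.11 on the Meis1 array, against 7.58 ± 0.00 in MIG, 7.52 ± 0.15 with miR-155, 8.03 ± 0.07 in the knockout and 6.92 ± 0.26 in MIY. The level of miR-155 itself was not measured, because no probe set is named for it. The MIG and knockout arrays were nearly alike, with correlations of 0.987 to 0.990 between the groups and of 0.988 to 0.990 within MIG. The MIY arrays stood apart from all others. They correlated at 0.980 with each other, at 0.952 to 0.966 with MIG and at 0.936 to 0.945 with the Meis1 array. The first principal component held 43.7% of the variance and separated MIY, and the second held 25.7% and separated the Meis1 array.

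**Figure D1:**
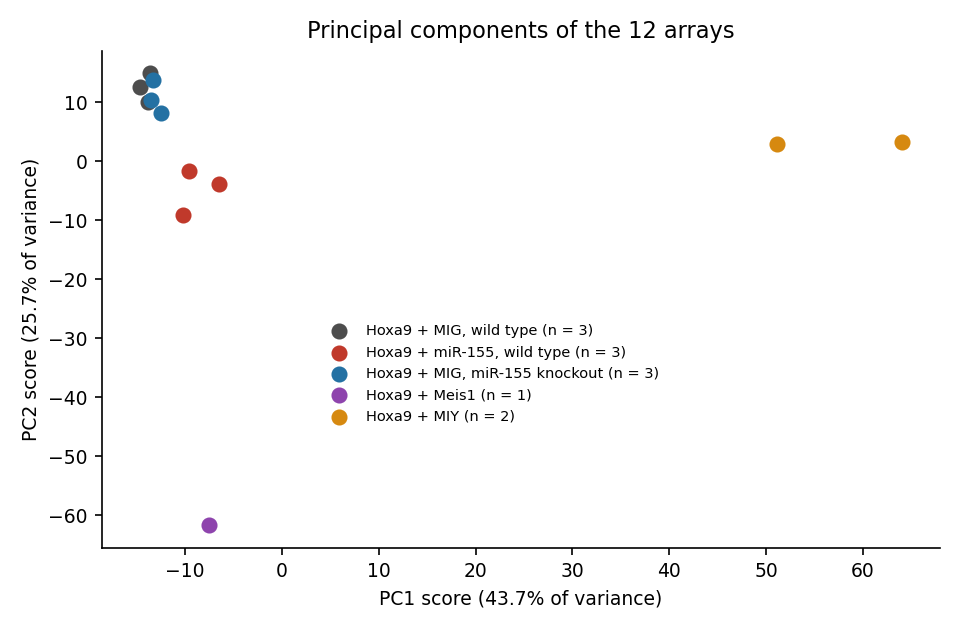
Scores of the 12 arrays on the first (43.7% of variance) and second (25.7%) principal components, 1 point per array, coloured by group. The 2 MIY arrays score 51.1 and 64.0 on the first component and the Meis1 array scores -61.7 on the second.

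All donor mice were labelled female, yet the Y-linked genes Eif2s3y and Kdm5d were high on 3 arrays, both MIY arrays and the Meis1 array. Eif2s3y read 9.23 and 9.31 on the MIY arrays and 8.24 on the Meis1 array, against 2.22 to 2.48 on the other 9. Kdm5d read 8.05 and 8.15 on the MIY arrays and 6.89 on the Meis1 array, against 3.32 to 3.50 on the other 9. Interferon-stimulated genes split the arrays another way. Mx1, an antiviral GTPase, averaged 9.13 ± 0.26 in MIY (n = 2) and 3.28 ± 0.21 in MIG (n = 3), and read 2.57 on the Meis1 array. Ifit1, which binds viral RNA, averaged 9.24 ± 0.57 in MIY and 4.56 ± 0.50 in MIG, and read 3.96 on the Meis1 array. The lowest of these levels lie in the low range of the arrays, whose minima were 0.535 to 1.09, and no measure of background was used here, so the sizes of changes from such levels are inexact. Every comparison that involves MIY or Meis1 also compares arrays that differ in Y-linked genes.

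**Figure D2:**
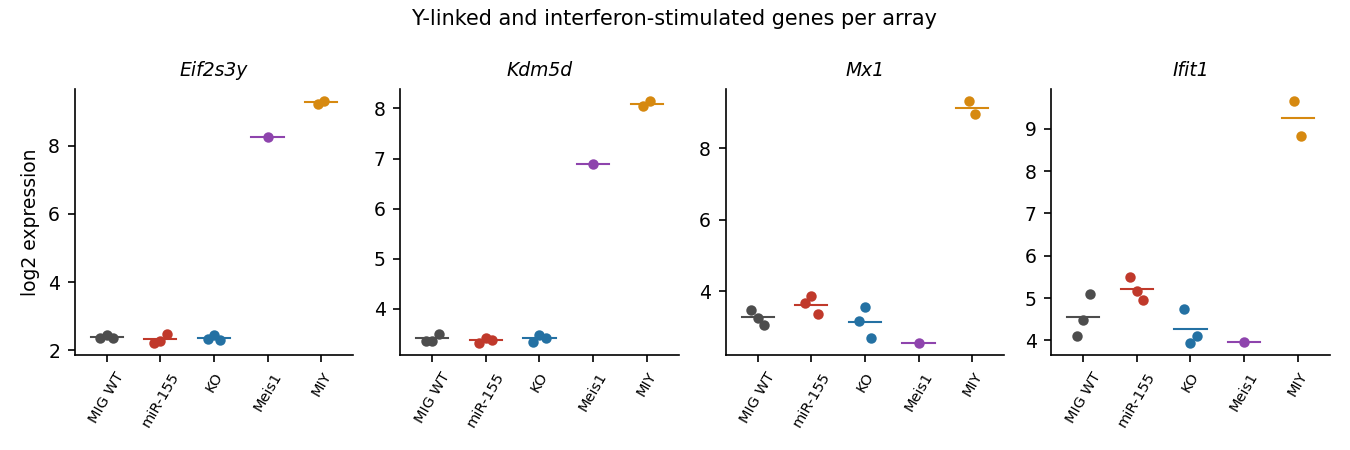
Expression (log2) of Eif2s3y, Kdm5d, Mx1 and Ifit1 on each array (points) with group means (lines). The Y-linked genes Eif2s3y and Kdm5d are high on the MIY and Meis1 arrays, whereas Mx1 and Ifit1 are high on the MIY arrays alone, with Mx1 means of 9.13 in MIY and 3.28 in MIG.

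The comparison of Hoxa9 plus miR-155 with Hoxa9 plus MIG asks what added miR-155 changes in Hoxa9 cells of the same naming series. Prss34, a serine protease of basophils and mast cells, fell from 10.01 ± 0.10 (SD, n = 3) to 7.89 ± 0.15 (n = 3), a log2 change of -2.12 ± 0.09 (SE, limma adjusted p = 4.35e-06), and the mast cell chymase Cma1 fell by 2.03 ± 0.19 on the log2 scale. The eosinophil granule proteins Prg2 (-2.21 ± 0.30) and Epx (-2.13 ± 0.25) fell by as much, as did the macrophage mannose receptor Mrc1 (-2.22 ± 0.38), the proton pump subunit Atp6v0d2 (-2.32 ± 0.19) and the cationic amino acid transporter Slc7a2 (-2.16 ± 0.12). The myeloid lectin receptors Clec4a3 and Clec4a1 changed by -1.91 ± 0.14 and -1.88 ± 0.24, and the collagenase Mmp13 by -1.88 ± 0.16. The rises were smaller. The casein genes Csn1s2a (1.47 ± 0.12) and Csn2 (0.98 ± 0.20), Vat1l (1.30 ± 0.10), Smpdl3b (1.18 ± 0.25), the defensin Defb39 (0.97 ± 0.21), Ifitm7 (0.95 ± 0.14), the TGF-beta coreceptor Eng (0.93 ± 0.12), Btla, Tulp3 and Irak1bp1 (each 0.87) headed them.

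Published direct targets of miR-155 were lower with miR-155. Of 35 measured targets, 13 fell and 0 rose in the test over all genes, and 22 fell when adjusted over the list alone, with a median log2 change of -0.33 (camera adjusted p = 5.52e-13, and adjusted p = 0.0192 with an estimated correlation). Jarid2, which recruits the Polycomb complex PRC2, fell from 9.42 ± 0.04 to 8.66 ± 0.04 (-0.76 ± 0.06, adjusted p = 0.000324). Tspan14 fell by 0.67 ± 0.09, the transcriptional repressor Bach1 by 0.53 ± 0.07, and Inpp5d, the inositol phosphatase SHIP1, by 0.39 ± 0.06. The myeloid transcription factors Spi1 (PU.1) and Cebpb fell by 0.50 ± 0.12 (adjusted p = 0.0496) and 0.46 ± 0.10 (adjusted p = 0.0389). Socs1, an inhibitor of cytokine signalling, had a change of -0.26 ± 0.07 that did not pass (adjusted p = 0.105). Hoxa9 (-0.03 ± 0.06) and Meis1 (-0.06 ± 0.10) did not pass either.

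**Figure D3:**
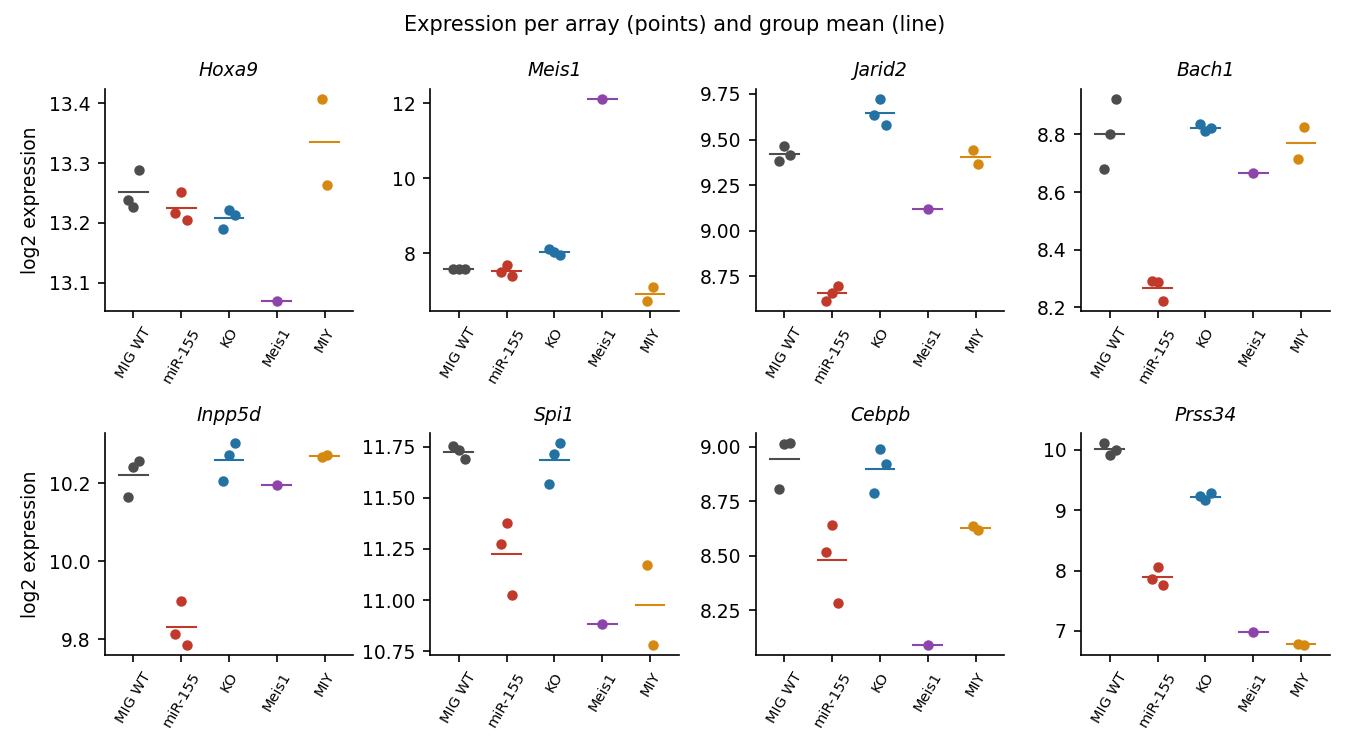
Expression (log2) of Hoxa9, Meis1, 5 targets of miR-155 (Jarid2, Bach1, Inpp5d, Spi1 and Cebpb) and the protease gene Prss34 on each array (points) with group means (lines). Jarid2 averages 8.66 with miR-155, 9.42 in MIG and 9.65 in the knockout, and Meis1 reads 12.11 on the Meis1 array.

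Mast cell and basophil genes were lower. Of 16 measured, 11 fell (14 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 1.04e-20, and adjusted p = 0.00994 with an estimated correlation). Mcpt8, a basophil protease, fell by 1.30 ± 0.11 and the mast cell carboxypeptidase Cpa3 by 1.13 ± 0.09. Monocyte and macrophage genes had a median of -0.65, with 9 of 20 lower (15 over the list alone), among them fibronectin Fn1 (-1.09 ± 0.11), cathepsin Ctss (-0.86 ± 0.09) and Cd68 (-0.67 ± 0.10). Their camera adjusted p was 1.27e-11, and their adjusted p = 0.134 with an estimated correlation. Eosinophil genes had a median of -0.79, with 4 of 8 lower (6 over the list alone), including Prg3 (-1.38 ± 0.22) and Siglecf (-0.96 ± 0.08), at a camera adjusted p of 1.43e-07 and an adjusted p = 0.0917 with an estimated correlation. Of 20 late granulocyte genes, lactoferrin Ltf (-1.25 ± 0.27) and Lrg1 (-0.91 ± 0.19) fell (6 genes over the list alone), at a camera adjusted p of 3.27e-05 and an adjusted p = 0.237 with an estimated correlation. Of 12 primary granule genes, Nkg7 (-0.92 ± 0.17) and Gfi1 (-0.42 ± 0.10) fell (3 over the list alone; camera adjusted p = 0.0257, and adjusted p = 0.447 with an estimated correlation). Of 13 MHC class II and dendritic cell genes, only the invariant chain Cd74 fell (-1.11 ± 0.16; 4 over the list alone), at a camera adjusted p of 0.0375 and an adjusted p = 0.237 with an estimated correlation. The primary granule list did not pass without MIG array 1 (camera adjusted p = 0.167), nor did the MHC class II list without MIG array 1 (0.103), MIG array 2 (0.0772) or miR-155 array 3 (0.0637), or in the fit on 9 arrays (0.0623).

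Inflammatory and immediate early genes were lower as well. Of 19 inflammatory genes, the chemokines Ccl2 (-1.50 ± 0.34) and Cxcl2 (-0.91 ± 0.19) and the cytokines Il6 (-1.48 ± 0.18) and Il1a (-1.22 ± 0.23) fell (7 genes over the list alone), at a camera adjusted p of 1.39e-06 and an adjusted p = 0.134 with an estimated correlation. Of 16 immediate early and heat shock genes, Egr2 (-1.42 ± 0.14), the phosphatase Dusp1 (-0.82 ± 0.14) and Atf3 (-0.77 ± 0.10) fell, and 10 were lower and 1 higher over the list alone, at a camera adjusted p of 6.07e-07 and an adjusted p = 0.205 with an estimated correlation. Interferon-stimulated genes had a median of 0.30, where Ifi27l2a alone rose (0.72 ± 0.12; 5 of 15 over the list alone), at a camera adjusted p of 1.08e-05 and an adjusted p = 0.205 with an estimated correlation. All 16 cholesterol synthesis genes had positive changes, with a median of 0.28, yet 0 passed over all genes and 1 over the list alone. Hmgcs1, an early enzyme of the pathway, had 0.53 ± 0.13 (adjusted p = 0.0615), and the list had a camera adjusted p of 8.02e-07 and an adjusted p = 0.277 with an estimated correlation. In the cell cycle list of 26 genes, the mitotic kinase Aurka rose (0.37 ± 0.07) and E2f2 fell, with 4 up and 2 down over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.588 with an estimated correlation). The cell cycle list did not pass without MIG array 2 (0.0636), MIG array 3 (0.205) or miR-155 array 2 (0.0923), nor with the replicate number as a block (0.0535) or in the fit on 9 arrays (0.0514). The other 7 lists did not pass. In them, Hlf and Hoxa7 rose and Gata2 and Kit fell among 22 stem and progenitor genes, Eya1 and Hlf rose among 22 Hoxa9 and Meis1 leukaemia genes, Gata1, Itga2b and Vwf fell among 14 red cell and megakaryocyte genes, Il7r fell among 15 lymphoid genes, Sesn1 rose and Plk2 fell among 18 p53 targets, and none of 17 stromal or 17 hypoxia and glycolysis genes passed.

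In all, limma called 527 of 16015 genes, 98 higher and 429 lower with miR-155, of which 4 rose and 97 fell at least 2-fold. The split moved with the scaling, to 217 up and 428 down after quantile normalization and 218 up and 361 down on a common array median. Leaving out 1 array left 228 to 398 genes called, and 19 of the 48 called genes that the naming rule took lost their call in at least 1 of these 6 runs, among them Mrc1, Csn2, Smpdl3b, Defb39, Btla, Tulp3, Ccl2, Cxcl2, Ltf, Lrg1, Spi1 and Cebpb.

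**Figure D4:**
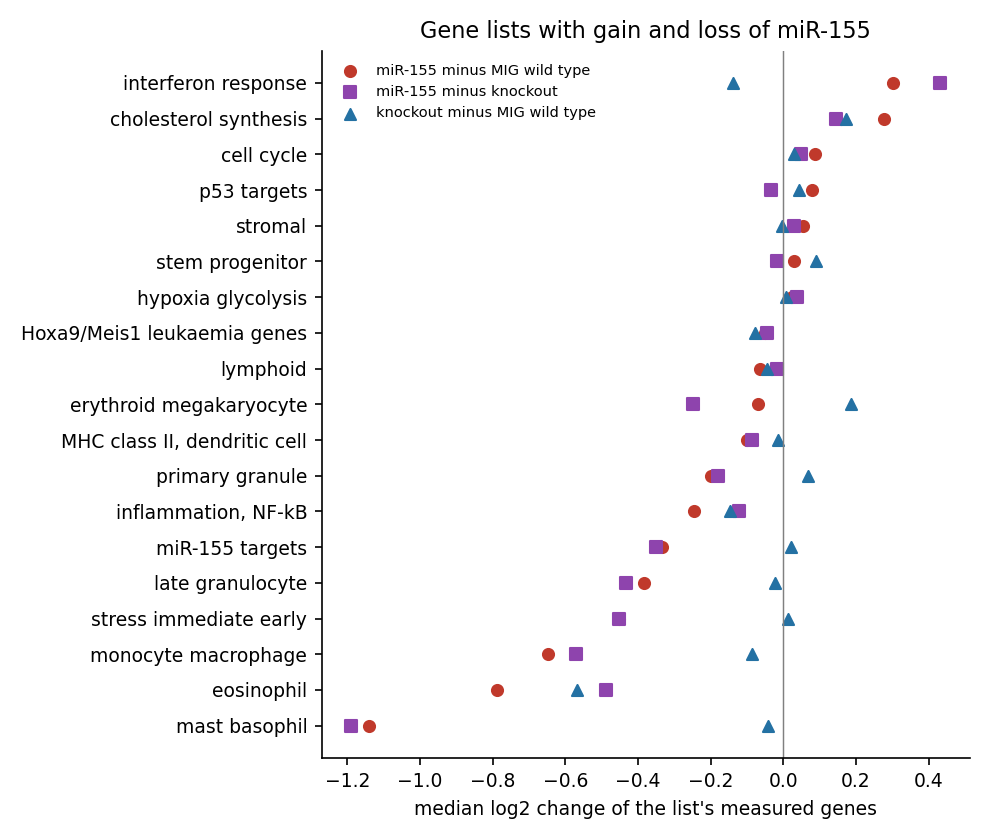
Median log2 change (horizontal axis) of the measured genes of each of 19 gene lists (vertical axis) for miR-155 minus MIG (circles), miR-155 minus knockout (squares) and knockout minus MIG (triangles). The mast cell and basophil list lies at -1.14 and -1.19 in the comparisons with miR-155, and the miR-155 targets at -0.33, -0.35 and 0.02.

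The comparison of the miR-155 knockout with MIG asks what Hoxa9 cells lose without their own miR-155. Few genes changed. Gucy1b1, a subunit of the nitric oxide receptor guanylate cyclase, rose by 0.75 ± 0.07 (limma adjusted p = 0.00704), the kinesin Kif21a by 0.80 ± 0.10 (adjusted p = 0.0366) and the serpin Serpina3b by 1.07 ± 0.13 (adjusted p = 0.0366). Prss34 fell by 0.78 ± 0.09 (adjusted p = 0.0318) and the protocadherin Pcdh7 by 0.56 ± 0.07 (adjusted p = 0.0366). Targets of miR-155 did not pass. Of the 35 measured, 0 passed over all genes or over the list alone, with a median of 0.02 and a camera adjusted p of 0.189. Jarid2 had 0.23 ± 0.06 (adjusted p = 0.767), Bach1 0.02 ± 0.07, Inpp5d 0.04 ± 0.06, Spi1 -0.04 ± 0.12, Cebpb -0.04 ± 0.10, Socs1 -0.04 ± 0.07 and Meis1 0.45 ± 0.10 (adjusted p = 0.552).

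Of the 19 lists, 8 passed camera at the preset correlation and 0 with an estimated one, and Prss34 was the only list member that passed over all genes. The red cell and megakaryocyte list had the smallest p, with a median of 0.19 (camera adjusted p = 4.64e-06, and adjusted p = 0.209 with an estimated correlation), where the platelet genes Itga2b and Gp9 had 0.37 ± 0.09 and 0.46 ± 0.14. Eosinophil genes had a median of -0.57 (camera adjusted p = 0.00016, and adjusted p = 0.387 with an estimated correlation), where Epx had -1.03 ± 0.25 (adjusted p = 0.577). Cholesterol synthesis genes had a median of 0.17 (camera adjusted p = 0.00016, and adjusted p = 0.655 with an estimated correlation), with 15 of 16 values positive. Interferon-stimulated (median -0.14, camera adjusted p = 0.0129), primary granule (0.07, 0.0175), monocyte and macrophage (-0.09, 0.0334) and inflammatory genes (-0.15, 0.0388) each had an adjusted p = 0.655 with an estimated correlation. The cell cycle list had 0.03, with a camera adjusted p of 0.0388 and an adjusted p = 0.66 with an estimated correlation. In runs without 1 array the interferon-stimulated, primary granule, monocyte and macrophage, inflammatory, cholesterol and cell cycle lists each lost their call at least once. Without MIG array 3 the primary granule list had 0.03, the cholesterol list 0.08 and the cell cycle list -0.01. Without knockout array 1 the monocyte and inflammatory lists had -0.05 and -0.06, and without knockout array 3 the interferon-stimulated list had -0.06. Limma called 5 of 16015 genes, 3 higher and 2 lower, and 774 had an unadjusted p under 0.05. Leaving out 1 array left 0 to 3 calls, and each of the 5 genes lost its call in at least 1 of the 6 runs. With the replicate number as a block 0 of the 5 calls were kept. A common array median also gave 5 calls, 4 higher and 1 lower, of which 4 were shared with the 5 above.

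The comparison of miR-155 with the knockout sets added miR-155, per the labels, against its absence. It uses the same miR-155 arrays as the comparison with MIG, so whatever sets those 3 arrays apart enters both. Csn2 (2.09 ± 0.20) and Csn1s2a (2.05 ± 0.12) rose most, followed by Vat1l (1.68 ± 0.10), Smpdl3b (1.66 ± 0.25), the retinaldehyde dehydrogenase Aldh1a3 (1.52 ± 0.16), Pcdh7 (1.36 ± 0.07, limma adjusted p = 3.02e-05), the acid-sensing receptor Gpr65 (1.24 ± 0.14), Cypt4, Polr2h and Cltb. The largest falls were those of Mrc1 (-2.21 ± 0.38), Slc7a2 (-2.05 ± 0.12), granzyme Gzmb (-1.93 ± 0.38), Plbd1 (-1.85 ± 0.17), Cma1 (-1.81 ± 0.19), Pla2g7 (-1.81 ± 0.22), Atp6v0d2 (-1.79 ± 0.19), Tph1, which makes serotonin in mast cells (-1.79 ± 0.23), Clec4a3 and Il1f9. Jarid2 fell by 0.99 ± 0.06 (adjusted p = 5.77e-05). Meis1 also fell, by 0.51 ± 0.10 (adjusted p = 0.0258), a call that was lost in runs without 1 array.

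The targets of miR-155 and the mast cell and basophil genes were the lists whose calls held with an estimated correlation. Of 35 targets, 11 fell (22 over the list alone), with a median of -0.35 (camera adjusted p = 2.75e-14, and adjusted p = 0.0145 with an estimated correlation). Tspan14 fell by 0.77 ± 0.09, Zfp652 by 0.66 ± 0.10, Bach1 by 0.55 ± 0.07 and Inpp5d by 0.43 ± 0.06, whereas Spi1 (-0.46 ± 0.12, adjusted p = 0.063), Cebpb (-0.42 ± 0.10, adjusted p = 0.052) and Socs1 (-0.22 ± 0.07) did not pass. Of 16 mast cell and basophil genes, 11 fell (13 over the list alone), with a median of -1.19 (camera adjusted p = 5.92e-18, and adjusted p = 0.0145 with an estimated correlation). Mcpt8 fell by 1.38 ± 0.11, Prss34 by 1.34 ± 0.09, the monoamine transporter Slc18a2 by 1.18 ± 0.11 and Cpa3 by 1.09 ± 0.09.

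Interferon-stimulated genes were higher with miR-155 than in the knockout, with a median of 0.43. Of 15, 5 rose (10 over the list alone), namely Oasl2 (0.92 ± 0.16), Cxcl10 (0.82 ± 0.17), Ifit2 (0.73 ± 0.16), Ifi27l2a (0.65 ± 0.12) and Rsad2, at a camera adjusted p of 2.36e-08 and an adjusted p = 0.149 with an estimated correlation. Red cell and megakaryocyte genes were lower, where Gata1 (-0.86 ± 0.10), the platelet integrin Itga2b (-0.74 ± 0.09), Gp9 (-0.65 ± 0.14) and Vwf (-0.58 ± 0.07) fell among 14, and 5 fell and 1 rose over the list alone (camera adjusted p = 7.78e-05, and adjusted p = 0.149 with an estimated correlation). Monocyte and macrophage genes had 8 lower, 1 higher (Cx3cr1) and 11 unpassed of 20, and 13 lower and 1 higher over the list alone, with a median of -0.57 (camera adjusted p = 1.12e-07, and adjusted p = 0.211 with an estimated correlation). Fn1 fell by 0.93 ± 0.11 and Ctss by 0.78 ± 0.09. Immediate early genes had 5 of 16 lower (9 over the list alone, with 1 higher), including Egr2 (-1.40 ± 0.14), at a camera adjusted p of 1.14e-06 and an adjusted p = 0.211 with an estimated correlation.

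The remaining myeloid lists pointed the same way and lost their calls with an estimated correlation. Late granulocyte genes had 4 of 20 lower (5 over the list alone), Ltf by -1.43 ± 0.27 and Il1b by -1.11 ± 0.19 (camera adjusted p = 4.48e-05, and adjusted p = 0.233 with an estimated correlation). Primary granule genes had 3 of 12 lower (4 over the list alone), Nkg7 by -1.27 ± 0.17 (camera adjusted p = 0.000153, and adjusted p = 0.233 with an estimated correlation). Eosinophil genes had 3 of 8 lower (4 over the list alone), with Prg2 at -1.57 ± 0.30, Siglecf at -1.12 ± 0.08 and Epx at -1.10 ± 0.25 (camera adjusted p = 0.00419, and adjusted p = 0.233 with an estimated correlation). Inflammatory genes had 4 of 19 lower (6 over the list alone), with Il6 at -1.64 ± 0.18 (camera adjusted p = 0.00419, and adjusted p = 0.241 with an estimated correlation). Of 13 MHC class II and dendritic cell genes, H2-Aa (-1.31 ± 0.32) and Cd74 (-1.09 ± 0.16) fell (4 over the list alone; camera adjusted p = 0.00889, and adjusted p = 0.211 with an estimated correlation). Cholesterol synthesis genes had a median of 0.14 with 0 of 16 passing (camera adjusted p = 0.025, and adjusted p = 0.696 with an estimated correlation), and without miR-155 array 1 that list did not pass (0.0734). The other 7 lists did not pass. Limma called 651 of 16015 genes, 174 higher and 477 lower, of which 17 rose and 91 fell at least 2-fold. The split was 287 up and 487 down after quantile normalization and 314 up and 449 down on a common array median. Leaving out 1 array left 325 to 457 calls, and 19 of the 61 called genes that the naming rule took were lost in at least 1 of those runs.

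Gain and loss of miR-155 were also set against each other across genes. Only Pcdh7 was called in opposite directions, rising by 0.79 ± 0.07 with miR-155 and falling by 0.56 ± 0.07 in the knockout, where chance would give 0.0926 such genes. The call of Pcdh7 in the knockout held in 6 of 18 other settings and in 0 of the 6 runs without 1 array. Prss34 was called lower in both, where chance would give 0.0719 genes called in the same direction. These expected counts take the comparisons as independent. Both comparisons use the same MIG arrays, which alone make their changes correlate. The correlation across genes was 0.259, against 0.501 (0.471 to 0.540 in 100 simulations) for unchanged groups that share those arrays, and the covariance was 0.00913 against 0.00974 (0.00886 to 0.0112). Changes had the same sign in 61.6% of genes, against 66.7% (65.8% to 67.5%) in the simulations. The simulations drew all arrays with a spread shared by the 5 groups. The median SD was 0.089 in MIG, whose arrays alone are shared, 0.107 with miR-155 and 0.129 in MIY. The simulated covariance may thus be too high, and its range does not decide whether gain and loss oppose each other. The 3 MIG arrays were not divided to give gain and loss separate controls, and genes are not independent replicates.

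The comparison of miR-155 with MIY asks the same question against the control named in the series description, with the same miR-155 arrays. The median change of all genes was 0.21, so the changes of genes and lists are given relative to that shift. The largest falls were those of Eif2s3y at -7.15 ± 0.08, Ifi205 at -6.00 ± 0.26, Mx1 at -5.70 ± 0.23, the chemokine Ccl5 at -5.07 ± 0.27, Kdm5d at -4.94 ± 0.07, Ms4a6b at -4.74 ± 0.17, Ddx60 at -4.63 ± 0.15, Ifi27l2a, Oas2 and the RNA-binding protein Igf2bp3 at -4.37 ± 0.28. The largest rises were those of the macrophage lectin Mgl2 (3.54 ± 0.18), Tceal8 (3.37 ± 0.49), the carbonic anhydrase Car4 (2.93 ± 0.16), Fn1 (2.93 ± 0.12), Cpne8 (2.87 ± 0.23), Retnlg (2.49 ± 0.39), Serpinb2 (2.49 ± 0.20), Clu (2.39 ± 0.24), Serpinb10 (2.38 ± 0.19) and the lipoprotein lipase gene Lpl (2.37 ± 0.24). As deposited, Tceal8 had 4.75 without MIY array 1 and 2.40 without MIY array 2, and Retnlg 3.64 and 1.75. Fn1, which fell with miR-155 against MIG, had -4.00 in MIY against MIG relative to the shift.

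Against this control the targets of miR-155 were lower. Of 35, 22 fell and 2 rose (23 and 3 over the list alone), with a median of -0.37 (camera adjusted p = 7.66e-06, and adjusted p = 0.0359 with an estimated correlation). Jarid2 fell by 0.95 ± 0.06 (limma adjusted p = 5.7e-06), Sdcbp by 1.02 ± 0.09, Rps6ka3 by 0.98 ± 0.08, Tab2 by 0.95 ± 0.09, Bach1 by 0.71 ± 0.08 and Inpp5d by 0.64 ± 0.07. Relative to the shift, 13 targets were higher and 5 lower in MIY than in MIG. Jarid2, Sdcbp, Rps6ka3, Tab2 and Inpp5d were among the higher ones. As deposited, 8 targets were higher and 11 lower in MIY. Sdcbp, Rps6ka3 and Tab2 were called higher there too, so part of their falls here comes from MIY. Jarid2 and Inpp5d were not called higher as deposited, so for them a part from MIY rests on the shift. Cebpb (-0.35 ± 0.11, adjusted p = 0.0327) and Socs1 (-0.23 ± 0.08, adjusted p = 0.0456) fell, and Spi1 had 0.04 ± 0.13 (adjusted p = 0.817). Meis1 rose by 0.39 ± 0.12 (adjusted p = 0.0231). Hoxa9 had -0.11 ± 0.07 as deposited (adjusted p = 0.207) and was called only with the shift (-0.31, adjusted p = 0.00508), on a probe set near the top of the range. Cebpb (-0.15) and Socs1 (-0.02) were not called as deposited either (adjusted p = 0.316 and 0.833). Mast cell and basophil genes went the other way than against MIG, with 5 of 16 higher and 0 lower (the same counts over the list alone) and a median of 0.26 (camera adjusted p = 0.0196, and adjusted p = 0.449 with an estimated correlation). MIY itself had 14 of these 16 lower than MIG, with a median of -1.39 relative to the shift. Without the shift 17 targets fell and 5 rose, with an adjusted p = 0.0932 with an estimated correlation, and the mast cell list did not pass (camera adjusted p = 0.0512).

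Interferon-stimulated genes were lower in 15 of 15 cases, also over the list alone, with a median of -3.81 (camera adjusted p = 4.33e-19, and adjusted p = 0.0359 with an estimated correlation), including Oas2 (-4.53 ± 0.12), Rsad2 (-4.16 ± 0.14) and Mx2 (-3.77 ± 0.12). The same miR-155 arrays had medians of 0.30 against MIG and 0.43 against the knockout, and MIY had 4.11 against MIG. This difference thus stems from high levels on the MIY arrays and not from a fall with miR-155. Cholesterol synthesis genes were higher in 15 of 16 cases, also over the list alone, with a median of 1.21, among them Nsdhl (1.72 ± 0.18), Insig1 (1.33 ± 0.15) and Srebf2 (0.74 ± 0.09), at a camera adjusted p of 2.94e-09 and an adjusted p = 0.449 with an estimated correlation. Monocyte and macrophage genes had 11 lower and 3 higher of 20, such as Ms4a6c (-2.79 ± 0.15) and C1qb (-1.81 ± 0.22) (11 and 4 over the list alone; camera adjusted p = 0.0315, and adjusted p = 0.745 with an estimated correlation). Inflammatory genes had 9 lower and 2 higher of 19 (10 and 3 over the list alone), including Il1a (-2.22 ± 0.24) and Tnfaip3 (-2.17 ± 0.13), at a camera adjusted p of 0.0128 and an adjusted p = 0.449 with an estimated correlation. Of 18 p53 targets, 10 fell and 2 rose (the same over the list alone), with Trp53inp1 at -1.35 ± 0.22, which as deposited was -1.65 without MIY array 1 and -0.63 without MIY array 2 (camera adjusted p = 0.0315, and adjusted p = 0.745 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 7 fell and 1 rose (8 and 1 over the list alone), with Hk2 at -0.95 ± 0.08 (camera adjusted p = 0.0128, and adjusted p = 0.449 with an estimated correlation). As deposited, single MIY arrays carried 3 of these lists. Without MIY array 2 the p53 list had a median of -0.01 (camera adjusted p = 0.187) and the hypoxia list 0.01 (0.129), and without MIY array 1 the monocyte list had -0.25 (0.137). The other 11 lists did not pass. Relative to the shift, MIY against MIG had medians of -0.77 for cholesterol synthesis, 0.36 for hypoxia and glycolysis and 0.48 for p53 targets. With miR-155 against MIG these were 0.28, 0.02 and 0.08, so these differences also reflect levels on the MIY arrays. Monocyte and inflammatory genes had 0.05 and 0.23 in MIY, and -0.65 and -0.25 with miR-155 against MIG.

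Relative to the shift 6060 genes passed, 2917 higher and 3143 lower. As deposited 7737 of 16015 passed, 6160 higher and 1577 lower. Quantile normalization gave 3440 higher and 2831 lower and a common median 3701 and 2489, and Eif2s3y and Kdm5d were high on both MIY arrays.

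The comparison of Meis1 with both empty vectors asks what Meis1 adds to Hoxa9. It rests on 1 array with high Y-linked genes, whose title alone carries the mark 3w. Its errors and p-values borrow the spread of the other groups, because the spread between Meis1 cultures was not measured. The labels do not explain that mark, and a difference in culture time is not excluded. The median change of all genes was 0.11, so changes are given relative to that shift. Meis1 itself rose by 4.75 ± 0.14 (limma adjusted p = 5.1e-08). Hoxa9 had -0.22 ± 0.08 as deposited (adjusted p = 0.0709) and -0.18 ± 0.09 against MIG alone (adjusted p = 0.209), and was called with the shift (-0.34, adjusted p = 0.0138), on a probe set near the top of the range. The largest falls were those of the acute phase protein Saa3 at -6.03 ± 0.30, the arginase Arg1 at -5.88 ± 0.20, Ms4a6d at -5.87 ± 0.22, Mrc1 at -5.74 ± 0.51, Cd74 at -5.66 ± 0.22, the neutrophil collagenase Mmp8 at -5.64 ± 0.14, Clec4n at -5.62 ± 0.18, Mmp13 at -5.49 ± 0.21, Chil3 at -5.41 ± 0.47 and Ctss at -5.35 ± 0.11. After Meis1, the largest rises were Gpx8 (4.26 ± 0.29), Gulp1 (4.14 ± 0.16), Neto2 (3.81 ± 0.35), the adhesion molecule Vcam1 (3.63 ± 0.58), Glyat (3.46 ± 0.14), the glutamate receptor Gria2 (3.17 ± 0.12), Aqp8 (3.14 ± 0.23), P2rx3 (3.08 ± 0.40) and the drug transporter Abcb1a. The sizes and their order depend on the control. Against MIG alone Saa3 had -4.47, Arg1 -6.56, Mrc1 -6.55, Gpx8 3.38 and Gulp1 3.85.

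Late granulocyte genes were lower in 18 of 20 cases (19 over the list alone), with a median of -2.46 (camera adjusted p = 5.01e-15, and adjusted p = 0.0366 with an estimated correlation), including Il1b (-4.27 ± 0.25) and the granule protein Ngp (-3.64 ± 0.31). Mast cell and basophil genes were lower in 14 of 16 (the same over the list alone), with a median of -1.13 (camera adjusted p = 1.89e-09, and adjusted p = 0.0366 with an estimated correlation), including the histidine decarboxylase Hdc (-2.93 ± 0.21) and the IgE receptor chain Ms4a2 (-2.44 ± 0.26). Against MIY alone, however, the mast cell list had a median of -0.39 and Prss34, which fell by 1.52 ± 0.12 against both, did not pass (0.20 as deposited, adjusted p = 0.225, where the median change of all genes was 0.23). Inflammatory genes were lower in 14 of 19 (the same over the list alone), with a median of -0.97 (camera adjusted p = 4.39e-10, and adjusted p = 0.0366 with an estimated correlation), such as Il6 (-3.47 ± 0.24) and Il1a (-3.42 ± 0.29), and against MIG alone 12 were lower (adjusted p = 0.0643 with an estimated correlation). Interferon-stimulated genes were lower in 15 of 15, also over the list alone, with a median of -2.44 (camera adjusted p = 7.19e-16, and adjusted p = 0.0366 with an estimated correlation), which was -4.49 against MIY alone and -0.60 against MIG alone. Against MIG alone 3 of the 15 were lower (adjusted p = 0.45 with an estimated correlation). The targets of miR-155 had 16 of 35 lower and 0 higher (17 and 2 over the list alone), with a median of -0.31 (camera adjusted p = 9.68e-05, and adjusted p = 0.0366 with an estimated correlation), including Jarid2 (-0.41 ± 0.08), Socs1 (-0.62 ± 0.10), Spi1 (-0.58 ± 0.16) and Cebpb (-0.81 ± 0.13). Bach1 (-0.23 ± 0.10, adjusted p = 0.121) and Inpp5d (-0.17 ± 0.08, adjusted p = 0.176) did not pass. Without the shift the targets had an adjusted p = 0.0842 with an estimated correlation. Against MIG alone 7 of the 35 were lower (adjusted p = 0.135 with an estimated correlation), and Jarid2 did not pass there (adjusted p = 0.0523).

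The lists that follow lost their calls with an estimated correlation. Of 20 monocyte and macrophage genes, 17 fell and Adgre1 rose (18 and 1 over the list alone), with Csf1r, the receptor of the macrophage growth factor, at -4.20 ± 0.27, C1qb at -4.54 ± 0.27 and Fn1 at -4.22 ± 0.14, which was -6.22 against MIG alone and -2.00 against MIY alone as deposited (camera adjusted p = 5.53e-14, and adjusted p = 0.0587 with an estimated correlation). Eosinophil genes had 5 of 8 lower (7 over the list alone; camera adjusted p = 0.000117, and adjusted p = 0.108 with an estimated correlation), with Epx at -2.91 ± 0.33 (-4.36 against MIG alone and -1.24 against MIY alone as deposited). Immediate early genes had 11 of 16 lower and Hsph1 higher (14 and 1 over the list alone; camera adjusted p = 7.14e-07, and adjusted p = 0.117 with an estimated correlation), with Atf3 at -2.63 ± 0.14. Of 18 p53 targets, 10 fell (12 over the list alone; camera adjusted p = 9.54e-06, and adjusted p = 0.215 with an estimated correlation), with Btg2 at -2.80 ± 0.29 and Cdkn1a, the inhibitor p21, at -1.55 ± 0.14. Of 17 hypoxia and glycolysis genes, 6 fell (8 over the list alone; camera adjusted p = 0.000199, and adjusted p = 0.108 with an estimated correlation), with Ndrg1 at -1.32 ± 0.13. Red cell and megakaryocyte genes had 6 lower and Car2 higher of 14 (the same over the list alone; camera adjusted p = 0.00975, and adjusted p = 0.117 with an estimated correlation), with the platelet chemokines Ppbp at -3.76 ± 0.35 and Pf4 at -2.41 ± 0.35. Of 13 MHC class II and dendritic cell genes, 4 fell and Flt3 rose (the same over the list alone; camera adjusted p = 0.0475, and adjusted p = 0.215 with an estimated correlation). As deposited, these last 2 lists did not pass against MIY alone (camera adjusted p = 0.173 and 0.0784). Relative to the median of all genes, the red cell and megakaryocyte list had -0.09 against MIY and -0.28 against MIG, and the MHC class II and dendritic cell list -0.19 and -0.20.

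Cell cycle, cholesterol and stromal genes were higher on the Meis1 array. Of 26 cell cycle genes, 10 rose and E2f2 fell (13 and 1 over the list alone), with Tyms at 0.92 ± 0.21, Mcm2 at 0.74 ± 0.17 and Aurka at 0.47 ± 0.09 (camera adjusted p = 0.000128, and adjusted p = 0.274 with an estimated correlation). Of 16 cholesterol synthesis genes, 7 rose (8 over the list alone), with Nsdhl at 1.13 ± 0.21 (camera adjusted p = 0.000199, and adjusted p = 0.34 with an estimated correlation), and against MIG alone 0 of 16 passed at a camera adjusted p of 0.303. Of 17 stromal genes, Vcam1, Thy1 (1.45 ± 0.11), the leptin receptor Lepr (1.06 ± 0.15) and Cxcl12 (0.63 ± 0.10) rose (6 over the list alone; camera adjusted p = 0.00195, and adjusted p = 0.0705 with an estimated correlation). Against MIG alone Lepr (0.25 ± 0.17, adjusted p = 0.395), Mcm2 (0.52 ± 0.18, adjusted p = 0.0801) and Nsdhl (0.42, adjusted p = 0.274) did not pass. Among 22 stem and progenitor genes, Angpt1, Flt3, Hlf, Kit, Meis1, Msi2 and Myb rose and 4 fell, and the list did not pass (camera adjusted p = 0.0505). The Hoxa9 and Meis1 leukaemia genes, primary granule genes and lymphoid genes did not pass either. Relative to the shift, 3727 genes passed, 1532 higher and 2195 lower, and as deposited 4333 of 16015, 2742 higher and 1591 lower, or 5083 and 1319 on a common median. As deposited the count was 2460 against MIG alone and 7066 against MIY alone, where the median change of all genes was 0.01 and 0.23.

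The comparison of MIY with MIG sets 2 groups of Hoxa9 cells with different empty vectors against each other and so measures how far control cultures differ. The median change of all genes was -0.22, and changes are given relative to that shift. The Y-linked Eif2s3y (7.11 ± 0.08) and Kdm5d (4.91 ± 0.07) rose most together with Mx1 (6.08 ± 0.23), Ifi205 (5.96 ± 0.26), Ccl5 (5.88 ± 0.27), Ifi27l2a (5.31 ± 0.14), Ifit1 (4.91 ± 0.34), Ddx60 (4.73 ± 0.15), Oasl2 (4.63 ± 0.18) and Rsad2 (4.44 ± 0.14). Cpne8 (-4.07 ± 0.23), Slc7a2 (-4.04 ± 0.13), Mgl2 (-4.02 ± 0.18), Fn1 (-4.00 ± 0.12), the IgE receptor chain Fcer1a (-3.65 ± 0.32), Egr2 (-3.45 ± 0.15), Car4 (-3.34 ± 0.16), H2-Aa (-3.23 ± 0.36), Tceal8 (-3.05 ± 0.49) and Prss34 fell most. All 15 interferon-stimulated genes rose, also over the list alone, with a median of 4.11 (camera adjusted p = 1.11e-19, and adjusted p = 0.054 with an estimated correlation, or 0.0196 without the shift). Of 16 mast cell and basophil genes, 14 fell (15 over the list alone), with a median of -1.39 (camera adjusted p = 8.16e-10, and adjusted p = 0.0541 with an estimated correlation), including Mcpt8 (-2.09 ± 0.13), Slc18a2 (-1.34 ± 0.12) and Cpa3 (-1.15 ± 0.10).

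Of 16 cholesterol synthesis genes, 14 fell in MIY (the same over the list alone), with Nsdhl at -1.43 ± 0.18, Insig1 at -1.17 ± 0.15 and Sc5d at -0.95 ± 0.15 (camera adjusted p = 2.47e-06, and adjusted p = 0.423 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 9 rose and Tpi1 fell (11 and 1 over the list alone), with Ankrd37 at 1.31 ± 0.27 and the hexokinase Hk2 at 1.04 ± 0.08 (camera adjusted p = 0.00474, and adjusted p = 0.423 with an estimated correlation), and as deposited this list did not pass without MIY array 2 (median -0.05, camera adjusted p = 0.0953), nor did Ankrd37 (0.59, adjusted p = 0.0716). Among 18 p53 targets, 9 rose and 4 fell, with Fas at 1.44 ± 0.11 and Cdkn1a at 0.97 ± 0.11, and the list did not pass (camera adjusted p = 0.09, or 0.0046 without the shift and then 0.2 without MIY array 2). The targets of miR-155 did not pass as a list, with 13 higher and 5 lower of 35. Jarid2 rose by 0.21 ± 0.06 (adjusted p = 0.0259), although as deposited it had -0.01 ± 0.06. Meis1 fell by 0.43 ± 0.12 (adjusted p = 0.0149). Hoxa9 had 0.08 ± 0.07 as deposited (adjusted p = 0.333) and was called only with the shift (0.31, adjusted p = 0.00547). The remaining 13 lists did not pass. Relative to the shift, limma called 6172 genes, 3179 higher and 2993 lower, and as deposited 7921, 1457 higher and 6464 lower. Quantile normalization gave 3053 and 3269 and a common median 2848 and 3238.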

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

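The tests for other donor mice, for a batch of arrays or cultures and for a fall of mast cells alone were chosen only after the result was seen. Among the 7317 probe sets without a gene symbol, which no comparison used, 45 changed between miR-155 and MIG (13 higher and 32 lower) when limma's adjustment covered all 23332 probe sets. That is 0.615% of them, against 2.01% of the named ones.

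MIY and MIG arrays differed in 7921 genes although both hold Hoxa9 with an empty vector. The scaling of the arrays does not account for the large count, since the fewest calls under 3 other scalings were still 6086. Which genes were called did depend on it. Of the 7921 calls, 4726 were shared after quantile normalization, 4695 on a common array median and 4450 with the median-difference shift. Cells of other donor mice are a candidate explanation, because the gap between the lowest MIY and the highest MIG array was at least 4.55 on the log2 scale in both Y-linked genes measured. The Meis1 array had high Y-linked genes without the high interferon-stimulated genes of MIY, but it is a single array that also carries Meis1, so it settles nothing about the interferon genes. An array or culture batch cannot be told apart from the group, because the labels give no batch and the highest correlation of a MIY array with an array of another group was 0.966, against 0.980 between the MIY arrays.

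Mast cell and basophil genes fell with miR-155 against MIG and, with the same miR-155 arrays, against the knockout, but not against MIY. There, 5 of 16 were higher and 0 lower relative to the shift (adjusted p = 0.449 with an estimated correlation). As deposited the list did not pass against MIY (camera adjusted p = 0.0512). The MIY arrays were themselves low in these genes, with 14 of 16 lower than in MIG and a median of -1.39 relative to the shift. The missing fall against MIY thus also reflects the levels in MIY. A single outlying array does not account for the fall against MIG, since the median without each miR-155 array stayed at -1.04 or lower. A fall in mast cells and basophils alone could account for the mast cell and basophil genes, but not for genes of other lineages that fell. Of the monocyte and macrophage genes 9 of 20 (median -0.65) fell singly, as did 4 of 8 eosinophil genes (median -0.79). Both of these lists lost their camera calls with an estimated correlation. Smaller shares of several of these lineages and lower expression within cells both stay open, and neither was measured.

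Few genes changed with loss of miR-155. A larger spread among the knockout arrays does not account for it, since their median SD was 0.866 of that of the miR-155 arrays. Changes too small for 3 arrays per group may account for it in part. With 200 genes changed, the simulated comparison recovered 92% of genes changed 2-fold, which argues against many changes of that size. It recovered only 48% of log2 changes of 0.5, and that leaves smaller changes open. Where fewer genes change, the adjustment is stricter, so both shares would be lower and single 2-fold changes can be missed. Epx, lower by more than 2-fold in the knockout, did not pass. Low miR-155 in the MIG cells would give the same result and was not measured.

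Other divisions of the 6 arrays were also tested for each comparison of 3 with 3. The 10 splits are too few for a share under 0.05 in each case. A mixed split also puts any difference between the groups, whatever its cause, into the estimate of the spread. That lowers its calls, so the contrast in counts overstates the support. For miR-155 against MIG the real split gave 527 genes and the highest other 1, so 1 of the 10 splits reached the real count, the real split itself. For the knockout against MIG the values were 5 and 0, and for miR-155 against the knockout 651 and 0, again with 1 of 10 splits at the real count.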

How the results depend on the processing

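The settings chosen only after the results were seen were the shift of each array to a median difference of 0, Meis1 without the MIY arrays, the list fits on 9 arrays and the Meis1 lists with each control. For the genes named in miR-155 against MIG, 1036 values under other settings kept their side of the threshold, 111 lost a call and 84 gained one, and for miR-155 against the knockout these were 1143, 121 and 39. No call became a call in the opposite direction, and the 6 results whose direction turned by their own test stand at the end of this paragraph. List medians near 0 turned their sign in more cases where the call was lost, among them hypoxia and glycolysis genes without MIY array 2 (0.01 for miR-155 against MIY and -0.05 for MIY against MIG) and p53 targets in that last run (-0.07). Counts of called genes moved more, and where no cause is given the cause was not tested. Weights per array gave 989 genes for miR-155 against MIG, 4269 for miR-155 against MIY, 19 for the knockout, 1148 for miR-155 against the knockout and 4956 for MIY against MIG. A minimum of 1.5-fold, which can only remove genes, left 274 for miR-155 against MIG, 2992 against MIY, 342 against the knockout, 2198 for Meis1 and 3186 for MIY against MIG. An adjusted p under 0.1, which can only add genes, gave 856 for miR-155 against MIG and 984 against the knockout. With only the groups compared in the fit, the counts were 852 for miR-155 against MIG, 5082 against MIY and 11 for the knockout. With only the 9 arrays of the 3 numbered groups they were 1051 for miR-155 against MIG, 13 for the knockout and 1195 for miR-155 against the knockout. Testing only the upper level range gave 4264 for miR-155 against MIY and 4268 for MIY against MIG, where fewer genes were tested, and testing all probe sets gave 1 for the knockout. Against MIG alone the Meis1 count was 2460, of which 1998 were shared with the 4333, and against MIY alone it was 7066. As deposited, camera with an estimated correlation called 2 lists for miR-155 against MIG, 1 against MIY, 2 against the knockout, 0 for the knockout, 4 for Meis1 and 1 for MIY against MIG, whereas relative to the shift it called 2 for miR-155 against MIY, 5 for Meis1 and 0 for MIY against MIG. As deposited, fry called 0 for the knockout and 15 for MIY against MIG. Fry asks another question, whether a list's genes move one way, and its calls had the opposite direction to camera for lists that camera did not call, the Hoxa9 and Meis1 leukaemia list (median 0.14) and the MHC class II and dendritic cell list (0.12) for miR-155 against MIY, and the monocyte and macrophage list (-0.17) and the immediate early list (-0.40) for MIY against MIG. Prss34 turned to 0.20 on the Meis1 array against MIY alone, which did not pass, and Jarid2 in MIY against MIG, not called as deposited, was called at 0.21 with the median-difference shift.

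Leaving out 1 array left 228 to 398 genes for miR-155 against MIG, with 287, 229 and 228 without MIG arrays 1, 2 and 3 and 249 and 284 without miR-155 arrays 1 and 3. It left 0 to 3 for the knockout, and 325 to 457 for miR-155 against the knockout, with 325 and 375 without miR-155 arrays 1 and 3 and 383, 345 and 383 without knockout arrays 1 to 3. Fewer arrays enter these fits. The lists past camera ranged from 3 to 8 for the knockout and from 3 to 7 for MIY against MIG, and leaving out a MIY array leaves 1, which is assumed to vary like the other groups.

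Whether the replicate numbers pair the arrays of MIG, miR-155 and the knockout stays open, and the main fit did not pair them. Of 9 pairs of equal number, 4 had deviations that correlated above 0.1 (range -0.067 to 0.164), and 5 of 9 arrays matched best an array of their own number. The pairs of MIG with the knockout had 0.055, 0.164 and 0.112. With the replicate number as a block the counts were 1174 for miR-155 against MIG, 1309 for miR-155 against the knockout and 2 for the knockout, neither of them among its 5. Without the block the same 9 arrays gave 1051, 1195 and 13. The seed match alternatives were not run, since no genome was used here.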

Other observations

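The test of a shared direction with Meis1 was chosen only after the result was seen. A group of genes stood in the order that the labels imply for miR-155, whose level was not measured, with every knockout array on one side of every MIG array and every MIG array on the same side of every miR-155 array. Csn2 rose along this order from 10.90 ± 0.07 (log2, SD, n = 3) in the knockout through 12.01 ± 0.20 in MIG to 12.99 ± 0.04 with miR-155, and Aldh1a3 from 7.22 ± 0.13 through 8.15 ± 0.19 to 8.74 ± 0.31. Csn1s2a, Gpr65, Pcdh7 and Smpdl3b were ordered the same way, and Ndrg2, Csrp3, Golm2, Gfi1b, Itga2b, Selp, Alox12 and Ptprk the opposite way. These names were chosen after their values were seen. The test had asked whether this order holds more genes than the other orders of the 3 groups. It held 311 genes, 117 rising and 194 falling with miR-155, against 177 with MIG and the knockout exchanged and 29 with the remaining order, where 19.1 would come from chance. The genes are not independent, and the large difference of the miR-155 arrays gives both orders with miR-155 at an end more genes than chance, so only the excess of 311 over 177 bears on the loss of miR-155. Whether a graded response to miR-155 underlies that excess stays open. The targets of miR-155 gave it no support as a list, with a median of 0.02 in the knockout and 0 of 35 passing. Their values went both ways (20 positive and 15 negative), and the means of the target Jarid2 did follow the order. With 200 genes changed, the simulated comparison recovered only 48% of log2 changes of 0.5, and the share would be lower with fewer genes changed. Smaller rises could thus be missed. The covariance of gain and loss, at 0.00913, lay within the 0.00886 to 0.0112 of unchanged groups, simulated with a spread shared by the 5 groups. The correlation (0.259) and the share of equal signs (61.6%) lay below theirs (0.471 to 0.540 and 65.8% to 67.5%). None of these decides the question.

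The genes lower with miR-155 tended to be lower with Meis1 too. Of the 477 genes lower with miR-155 than in the knockout, 84.3% were lower on the Meis1 array than in MIG, against a mean of 50.2% and a highest share of 58.5% in 10000 random lists matched on mean level. Of these genes 303 were called lower with Meis1 and 20 higher, where 44.8 shared falls would come from independent lists, and the median change was -0.83. Of the 174 genes higher with miR-155 than in the knockout, 58.0% were higher with Meis1, a share reached by 162 of the 10000 lists, and 45 were called higher and 27 lower, where 10.4 shared rises would come from independent lists. Both comparisons use different arrays, so no shared control enters. The random lists and the expected counts treat genes as independent, whereas genes of one lineage move together. The estimated correlation was 0.41 within the monocyte and macrophage list. A single difference that moves many genes of the Meis1 array could give such shares, so they describe these arrays only. What the shared falls have in common was not tested. The Meis1 side rests on 1 array with high Y-linked genes, and a difference of donors or cultures was not separated from Meis1.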
